A study of Bos indicus with 55 samples.

How the data were processed

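Tissue and vesicles came from cattle on day 16 of pregnancy. Endometrium, the lining of the uterus, was profiled as poly(A) RNA in 27 libraries, and extracellular vesicles (EVs, small membrane particles that cells release) were profiled as small RNA in 28 libraries. Per the labels' protocols, each conceptus (the embryo with its developing membranes) released its EVs over 6 h of culture. Conceptuses were conceived in vivo after artificial insemination, made by in vitro fertilisation (IVF) or made by nuclear transfer, in which the nucleus of another cell replaces that of an egg. Groups were taken from the sample titles as conceptus type by conceptus sex. The animal number in the labels tied libraries to cows: 27 animals gave both materials and 1 further animal gave EVs alone. Each library is thus from a different animal within its material. Of the endometrium libraries, 3 came from the horn opposite the conceptus (contralateral) and the others from the same horn.

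Per the labels' protocols, RNA was extracted with silica columns and DNase treatment, endometrium libraries kept the strand through dUTP marking, and EV libraries were cut to a short insert size before sequencing. Per the submitters' processing notes, the genome build was ARS-UCD1.2 and the tools used included cutadapt, STAR, featureCounts, Bowtie and DESeq2. Their versions, their roles, the annotation release and the strand setting of the counting are not given in the sources used here. The labels give the organism as Bos indicus for every sample, while the series' design text assigns the conceptuses to Bos taurus taurus. A strain difference from the reference can lower counts of individual genes.

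The authors deposited the endometrium values as estimated counts per gene, not normalized: 85.2% of the values above 0 were whole within 0.004 and the others were fractions, as arise when a read is shared between places. They were rounded to whole numbers before any test. The table holds 27619 genes, of which 27607 have an Ensembl identifier and 12 a symbol, and the files do not pair the identifiers with names. The table of gene names used here matched 0 of the 27607 identifiers. Gene lists for the endometrium were fixed for 31 pathways and cell types, and 0 of them had a tested member, so all 31 tests are void, including interferon-stimulated genes and the markers of other cell types. Of the 12 symbols, TBL1X alone passed the filter.

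The authors deposited the EV values as whole counts of reads per miRNA, not normalized. The table lists 1024 bovine miRNAs, 655 of them with a count. Of the 655, 102 have the same counts in every library as another entry, and 12 of these were among the entries tested. Entries with few counts can match in this way without sharing reads. The abundant pairs miR-148a with miR-148d and let-7b with miR-3596 have the same counts and cannot be told apart. All sample columns of both tables were used.

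Counts were tested with edgeR 4.0.16 in R 4.3.3, with TMM scaling, filterByExpr (minimum count 10, minimum total 15) and the quasi-likelihood F test, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. All libraries of a material entered 1 fit of 6 group means. A contrast between conceptus types is the mean of the female and the male difference, the sex contrast is the mean of the 3 differences within types, and the interaction tests on 2 degrees of freedom whether type differences depend on sex. Standard errors were taken from the fold and its F statistic. CPM values given for groups or libraries were scaled by TMM, and log2 CPM values used a prior count of 2. Fitted log2 folds used the default prior count of the edgeR fit instead. Behind a number, k and M stand for kilo and mega. Gene lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, with an estimated correlation and fry beside it. Camera compares a list with the other miRNAs, while fry tests it against no change and does not bear on its rank. Pooled counts carry exact Poisson intervals at a confidence level of 95%, and these cover counting error alone.

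Contrasts, tests, gene lists, the alternatives planned and the rule for naming genes were fixed before the data were examined. The rule takes, from the genes or miRNAs past the threshold with a symbol and a mean log2 CPM of at least 1, the 10 with the largest rise and the 10 with the largest fall; where none passed, the 5 with the smallest p; up to 4 members of each list past the threshold; and the 10 most abundant EV miRNAs. Up to 5 were named for the interaction. Endometrial identifiers fall outside the rule, and those printed were chosen after their values were seen. Fits within 1 sex or 1 type were planned, and the pair of them described in detail was chosen after the number of calls was seen.

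Alternatives were DESeq2 1.42.0, limma voom with quality weights, DESeq2-style size factors, no low count filter, another EV filter (10 CPM in 3 libraries), library sizes without the 5 most abundant EV miRNAs, an additive model, a replicate block, subsets of types or sexes, leaving out the contralateral libraries, the horn as a covariate, and leaving out each library in turn. Added after seeing the data were thinning to equal depth, the sample code column as a covariate, leaving out in vivo male replicate 1 together with the contralateral libraries, counting identical EV entries 1 time, leaving out miR-2887 and miR-2904, and their share as a covariate. Simulated counts with known changes were used to test the fits: in the comparison of nuclear transfer with in vivo over 15911 endometrial genes, 74.6% of the 2-fold and 92.5% of the 4-fold changes were recovered. In the same EV comparison over 240 miRNAs these were 80.0% of the 4-fold and 100% of the 16-fold changes. In the EV comparison of IVF with in vivo, 20.0% of the 4-fold and 90.0% of the 16-fold changes were recovered. For sex within nuclear transfer EVs these were 40.0% and 100%. Each EV percentage rests on 10 changed miRNAs in 1 simulated draw, so it is imprecise. For nuclear transfer against in vivo within male endometrium, 50.7% of the 2-fold and 88.1% of the 4-fold changes were recovered. Of the 189 calls in that endometrial comparison over both sexes, 11 were false. Each gene or miRNA was drawn independently, without outlying libraries or changes shared between genes, so these rates can be better than real libraries allow.

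Endometrium libraries held 5.53 to 9.82 M counts (median 6.55 M) over 18780 to 19328 detected genes. EV libraries held 39.3 to 603.6 k counts (median 120.7 k) over 220 to 406 detected miRNAs, and the 10 most abundant miRNAs took 57.2 to 88.8% of them. The biological coefficient of variation was 0.255 in endometrium and 0.836 in EVs, so EV folds are far less precise. No 2 libraries of a group held the same values: the lowest chi-square per degree of freedom was 9.1 over 55 endometrium pairs and 33.6 over 61 EV pairs.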

Results

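Endometrium was sequenced under 6 in vivo conceptuses (3 female, 3 male), 10 IVF conceptuses (7 female, 3 male) and 11 nuclear transfer conceptuses (5 female, 6 male). EVs were sequenced from 6 in vivo conceptuses (3 female, 3 male), 10 IVF conceptuses (7 female, 3 male) and 12 nuclear transfer conceptuses (5 female, 7 male). Endometrium totals ran from 5.53 M counts to 9.82 M in in vivo male replicate 1, the next highest being 7.37 M. EV totals ran from 39.3 k in in vivo male replicate 2 to 603.6 k in nuclear transfer female replicate 3. The series title frames the question as whether the endometrium senses the kind of conceptus and whether EV miRNAs take part in this. The first principal component of endometrial log2 CPM held 16.7% of the variance and the second 12.6%, and in vivo male replicate 1 lay apart from all other libraries on the second.

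**Figure D1:**
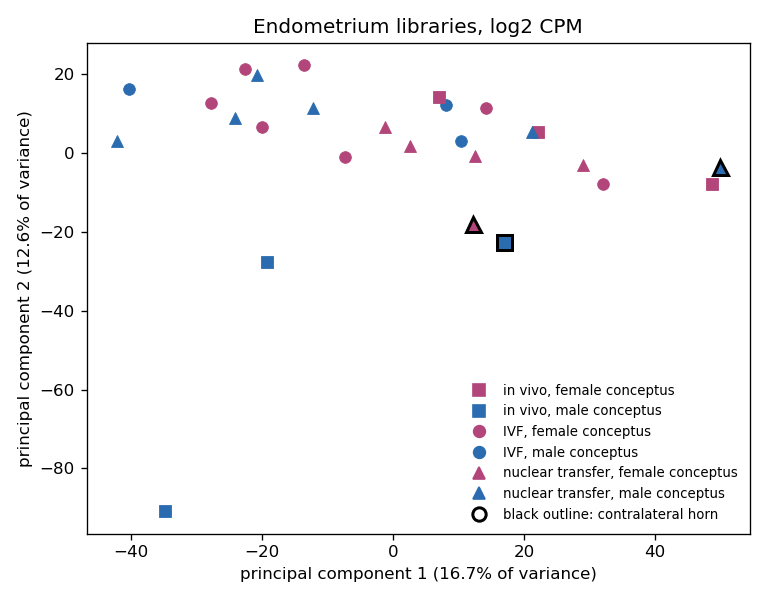
Endometrium libraries on the first (x axis, 16.7% of variance) and second (y axis, 12.6% of variance) principal components of log2 CPM; each point is 1 library, shape marks the conceptus type, colour its sex and a black outline the 3 contralateral libraries. The types overlap, and in vivo male replicate 1 has the lowest value on the second component.

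In endometrium under IVF conceptuses, 2 genes were lower than under in vivo conceptuses and none of the 15911 tested was higher by edgeR. ENSBTAG00000005433 fell by 2.67 on the log2 scale (SE 0.45, adjusted p = 0.0311 by edgeR). ENSBTAG00000000357 fell by 1.04 (SE 0.17, adjusted p = 0.0311 by edgeR). ENSBTAG00000005433 stood at 38.7 ± 7.05 CPM (SD, n = 3) under in vivo males, 3.98 ± 1.92 (n = 3) under in vivo females, 2.65 ± 2.04 (n = 7) under IVF females and 1.40 ± 1.2 (n = 3) under IVF males. ENSBTAG00000000357 stood at 43.8 ± 5.60 CPM under in vivo males, 23.7 ± 9.66 under in vivo females, 13.8 ± 3.45 under IVF females and 17.7 ± 3.87 under IVF males. TBL1X, a component of a nuclear receptor corepressor complex, averaged 22.1 ± 2.00 CPM (n = 6) under in vivo and 22.3 ± 1.76 (n = 10) under IVF conceptuses. The log2 difference was -0.01 (SE 0.10, adjusted p = 0.980 by edgeR). In all, 1698 genes lay at an unadjusted p under 0.05, where chance alone gives 795.6. The call of ENSBTAG00000005433 was lost in 6 of 14 alternatives and that of ENSBTAG00000000357 in 7 of 14, each in 12 of 27 fits with 1 library left out. DESeq2 called 89 genes (42 higher, 47 lower) and limma voom 11, while leaving out 1 library gave from 0 to 37.

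Under nuclear transfer conceptuses, endometrium showed 0 genes apart from in vivo by edgeR over both sexes, with 1407 at an unadjusted p under 0.05, 44 by DESeq2 and 2 by limma voom. Fitted within male conceptuses alone, 56 of 15296 genes changed by edgeR, 13 higher and 43 lower under nuclear transfer. ENSBTAG00000014218 rose by 5.05 on the log2 scale (SE 0.71, adjusted p = 0.0211 by edgeR). Its level went from 5.29 ± 2.18 CPM (n = 3) under in vivo males to 173 ± 88.5 (n = 6) under nuclear transfer males, with 187 ± 165 (n = 3) under IVF males. ENSBTAG00000009012 rose by 3.75 (SE 0.72, adjusted p = 0.0489 by edgeR), from 4.15 ± 0.787 CPM under in vivo males to 55.9 ± 39.1 under nuclear transfer males. It stood at 60.4 ± 45.0 CPM under IVF males and 63.7 ± 43.5 under IVF females. Under nuclear transfer females it stood at 43.5 ± 33.9 and under in vivo females at 24.4 ± 20.3, so in vivo males were the lowest group. Both genes were picked as the largest rises, and none of the 43 falls is described here. The call of ENSBTAG00000009012 was lost in 6 of 11 alternatives and in 10 of 12 fits with 1 library left out (adjusted p = 0.0383 to 0.280 by edgeR), and that of ENSBTAG00000014218 in 4 of 11 and in 2 of 12. Under female conceptuses ENSBTAG00000014218 stood at 99.0 ± 56.2 CPM (n = 3) in vivo and 102 ± 65.3 (n = 5) for nuclear transfer. Among female conceptuses 0 of 15487 genes passed by edgeR, with 726 at an unadjusted p under 0.05. TBL1X differed by 0.04 (SE 0.09, adjusted p = 0.938 by edgeR) over both sexes. The in vivo male libraries are the group farthest from the others on the second principal component. All 3 carry the digit 3 in their sample code and none of the nuclear transfer male libraries does. With 1 library left out the male count of 56 became 3, 216 and 21 without in vivo males 1, 2 and 3, male 2 being contralateral. It became 13, 5, 6 and 7 without nuclear transfer males 2, 3, 4 and 5, and 29, 30 and 30 without IVF males 1, 2 and 3. It was 501 by DESeq2, 48 by limma voom, 565 in the fit of all 6 groups and 0 with the sample code digit as a covariate.

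No endometrial gene passed the test between nuclear transfer and IVF conceptuses: edgeR called 0 genes, 348 lay at an unadjusted p under 0.05 against 795.6 by chance, and DESeq2 and limma voom called 0 each. ENSBTAG00000005433 stood at 3.96 ± 2.45 CPM (n = 5) under nuclear transfer females and 3.21 ± 1.68 (n = 6) under nuclear transfer males, next to 2.65 and 1.40 for IVF. TBL1X differed by 0.05 (SE 0.08, adjusted p = 1.00 by edgeR).

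Conceptus sex gave 0 endometrial genes by edgeR over the 3 types, with 2007 at an unadjusted p under 0.05, 57 by DESeq2 (21 higher, 36 lower under males) and 0 by limma voom. TBL1X differed by 0.02 (SE 0.07, adjusted p = 0.903 by edgeR). Of the Y-linked symbols, ZFY had 2 counts in 1 library and SRY, DDX3Y, USP9Y and EIF1AY had 0 in all 27. The type by sex interaction was past the threshold for 1 gene known by its identifier alone (adjusted p = 0.0141 by edgeR). It averaged 59.3 ± 19.8 CPM (n = 3) under in vivo males and 214 ± 76.2 (n = 3) under in vivo females. The other 4 groups lay between these values, at up to 154. Without the 3 contralateral libraries edgeR called 508 genes for sex (286 higher, 222 lower) and 277 for the interaction. Without in vivo male replicate 1 as well both counts were 0.

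EVs carried a mixed miRNA cargo dominated by a few entries. miR-2887 and miR-2904, entries listed beforehand as overlapping other small RNA classes, averaged 242 ± 155 and 174 ± 123 k CPM (n = 12) in nuclear transfer EVs, 334 ± 247 and 318 ± 270 k (n = 10) in IVF EVs and 125 ± 76.1 and 54.0 ± 45.6 k (n = 6) in in vivo EVs. These CPM are TMM-scaled and are not shares of the counts. Of the counts, the 2 entries together took 4.1 to 37.1% in in vivo, 8.8 to 76.3% in IVF and 5.2 to 59.4% in nuclear transfer libraries. The abundant miRNAs proper were miR-148a at 72.9 ± 36.7, 73.6 ± 21.6 and 99.2 ± 37.2 k CPM for in vivo, IVF and nuclear transfer, let-7a-5p at 67.5 ± 65.5, 33.7 ± 26.2 and 47.6 ± 45.0 k, and miR-26a at 34.6 ± 19.9, 30 ± 12.3 and 37.7 ± 19.5 k. miR-21-5p averaged 20.6 ± 8.26, 23.7 ± 7.38 and 21.8 ± 5.64 k CPM. None of the 10 most abundant entries passed the test between types.

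In IVF EVs, no miRNA passed the test against in vivo by edgeR: 0 of 240, with 39 at an unadjusted p under 0.05 where chance gives 12. DESeq2 called 10 (9 higher, 1 lower) and limma voom 22 (6 higher, 16 lower). The smallest p belonged to miR-2892 with a log2 difference of 4.31 (SE 1.2), from 152 ± 241 CPM (n = 6) in vivo to 2511 ± 2147 (n = 10) in IVF. Next came miR-320a at -1.48 (SE 0.42), from 3970 ± 1759 CPM to 1499 ± 666.0. miR-2404 at 3.79 (SE 1.13), miR-2904 at 2.56 (SE 0.77) and miR-12034 at 3.61 (SE 1.12) followed. All 5 had an adjusted p = 0.140 by edgeR. Of these, miR-2892 and miR-2904 are on the list of entries that overlap other small RNA classes. As a group, the miR-10 and miR-99 or 100 families ranked lower in IVF EVs than other miRNAs (camera adjusted p = 0.0173), a call lost at adjusted p = 0.737 with an estimated correlation. None of the 7 members had a positive difference: miR-125a was at -1.35 (SE 0.63), miR-10a at -1.08 (SE 0.74), miR-99b at -1.04 (SE 0.52) and miR-125b at -0.71 (SE 0.50). Past the threshold were 0 over all miRNAs and 0 adjusted over the list alone. Without IVF male replicate 3 edgeR called 21 miRNAs.

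In nuclear transfer EVs, miR-1298 was lower than in in vivo EVs and was the 1 miRNA of 240 past the threshold. Its log2 fold was -5.75 (SE 1.32, adjusted p = 0.0389 by edgeR), a size that depends on the default prior count of the fit because 9 of the 12 nuclear transfer libraries had no count. Pooled over libraries it held 77 counts in 4 of 6 in vivo EVs, 10.4 per 100k (95% interval 8.23 to 13). It held 4 counts in 3 of 12 nuclear transfer EVs, 0.206 per 100k (0.0562 to 0.528). The miR-10 and miR-99 or 100 families again ranked lower (camera adjusted p = 0.000251; adjusted p = 0.250 with an estimated correlation), with 0 of 7 members positive. Past the threshold were 0 over all miRNAs and 2 adjusted over the list alone. miR-125b averaged 3.10 ± 0.927 k CPM (n = 6) in in vivo EVs and 1.31 ± 1.46 k (n = 12) in nuclear transfer EVs, a log2 difference of -1.26 (SE 0.46). miR-125a was at -1.53 (SE 0.57), miR-99b at -1.10 (SE 0.47) and miR-10b at -1.02 (SE 0.51). DESeq2 called 0 miRNAs and gave no p for miR-1298, and limma voom called 0. Leaving out 1 of 11 libraries ended the miR-1298 call (up to 5 calls without another).

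Against IVF EVs, nuclear transfer EVs were lower in 3 miRNAs of 240, namely miR-124a, miR-124b and miR-1298. miR-124, best known as an abundant miRNA of neurons, had a log2 fold of -6.57 (SE 1.58) for miR-124a and -5.88 (SE 1.46) for miR-124b, and miR-1298 had -5.24 (SE 1.27), each with an adjusted p = 0.0466 by edgeR. These sizes depend on the default prior count of the fit, because most nuclear transfer libraries had no count. miR-124a held 146 counts in 5 of 10 IVF EVs, 10.8 per 100k (95% interval 9.14 to 12.7). It held 96 counts in 4 of 6 in vivo EVs, 13 per 100k (10.5 to 15.9), and 8 counts in 1 of 12 nuclear transfer EVs, 0.413 per 100k (0.178 to 0.813). In all 28 libraries the miR-124a count lay within 1 of 2 times the miR-124b count, so that pair is 1 measurement. miR-1298 held 69 counts in 5 of 10 IVF EVs, 5.12 per 100k (3.98 to 6.48). Most of the signal came from few libraries: miR-124a reached 150 per 100k in IVF male replicate 3 and 51.0 in IVF female replicate 4, and 5.53 or less in the other 8 IVF libraries.

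**Figure D2:**
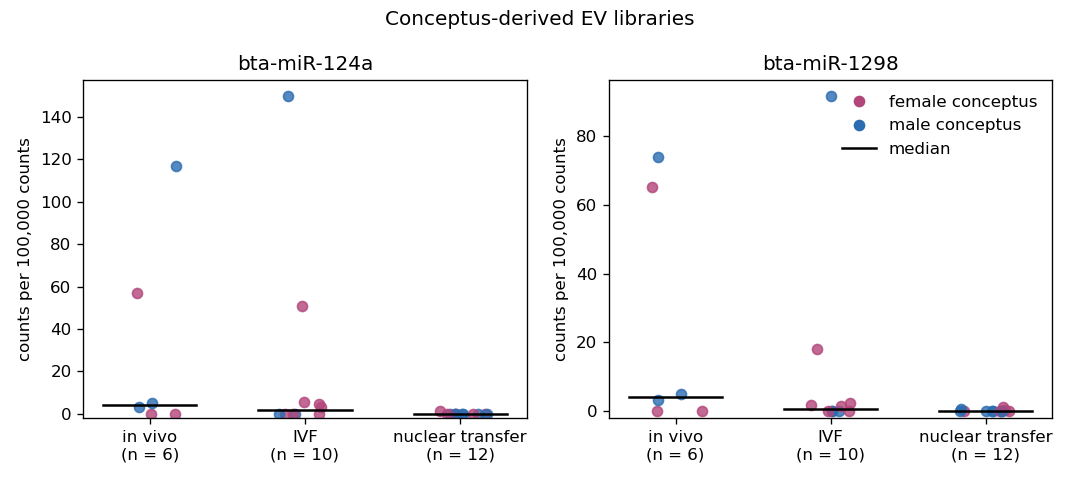
Counts of miR-124a (left) and miR-1298 (right) per 100k counts (y axis) in each EV library by conceptus type (x axis); points are libraries coloured by conceptus sex and bars are medians. A few in vivo and IVF libraries reach 51.0 to 150 per 100k for miR-124a, while the highest nuclear transfer library reaches 1.33.

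Among the lists, the miR-302 and miR-371 clusters, typical of pluripotent and early embryonic cells, ranked lower in nuclear transfer than in IVF EVs (camera adjusted p = 0.0405; adjusted p = 0.479 with an estimated correlation). All 5 members were negative, with 0 past the threshold over all miRNAs and 0 adjusted over the list alone. That call was kept in 8 of 11 alternatives, turning direction in 1, and in 17 of 28 fits with 1 library left out. miR-302b averaged 779 ± 968 CPM (n = 12) in nuclear transfer and 1744 ± 1770 (n = 10) in IVF EVs, at -1.78 (SE 0.75), miR-302a was at -1.97 (SE 0.85) and miR-371 at -1.93 (SE 0.88). The miR-29 and miR-30 families ranked higher (camera adjusted p = 0.0414; adjusted p = 0.479 with an estimated correlation), with 8 of 9 members positive. That call was kept in 5 of 11 alternatives, turning direction in 1, and in 7 of 28 fits with 1 library left out (adjusted p = 0.0209 to 0.246 by camera). miR-30d was at 0.66 (SE 0.32), miR-30f at 1.42 (SE 0.68) and miR-29b at 1.51 (SE 0.74), and 0 past the threshold by either adjustment, over all miRNAs or adjusted over the list alone. The ruminant miR-2284 and miR-2285 families ranked higher as well (camera adjusted p = 0.0414; adjusted p = 0.479 with an estimated correlation), with all 4 members positive. The call was kept in 4 of 11 alternatives and in 6 of 28 fits with 1 library left out (adjusted p = 0.0105 to 0.411 by camera). miR-2285av was at 1.34 (SE 0.78) and miR-2284y at 0.94 (SE 0.79), and 0 past the threshold, 0 adjusted over the list alone. DESeq2 and limma voom called 0 miRNAs between nuclear transfer and IVF, DESeq2 giving no p for miR-124a and miR-1298. Leaving out any of 15 libraries ended all 3 edgeR calls. The calls also ended without miR-2887 and miR-2904 in the table or with their share as a covariate.

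Over the 3 types, conceptus sex gave 0 EV miRNAs by edgeR (9 at an unadjusted p under 0.05, where chance gives 12), 0 by DESeq2 and 0 by limma voom. The smallest p values belonged to miR-6516 at 1.74 (SE 0.66) and miR-432 at 1.63 (SE 0.65) higher in males, miR-138 at 2.34 (SE 0.95), miR-34c at -1.02 (SE 0.42) and miR-375 at -1.17 (SE 0.50), all at an adjusted p = 0.694 by edgeR. Of these, miR-6516 is on the list of entries that overlap other small RNA classes. miRNAs of the DLK1-DIO3 region, a large imprinted cluster, ranked higher in male EVs (camera adjusted p = 1.85e-05; adjusted p = 0.587 with an estimated correlation), with 15 of 16 members positive. miR-411a was at 1.13 (SE 0.49), miR-409b at 1.05 (SE 0.48) and miR-379 at 0.85 (SE 0.43), and 0 past the threshold over all miRNAs or adjusted over the list alone. In IVF EVs taken alone miR-411a was at -0.23 and miR-379 at -0.07. The DLK1-DIO3 call was kept in 9 of 11 alternatives and in 28 of 28 fits with 1 library left out. The miR-29 and miR-30 families ranked lower in males (camera adjusted p = 0.0129; adjusted p = 0.587 with an estimated correlation; 0 of 9 positive). So did the let-7 family, a group that accumulates as cells differentiate (camera adjusted p = 0.0414; adjusted p = 0.587 with an estimated correlation; 0 of 9 positive). The let-7 call was kept in 8 of 11 alternatives and in 12 of 28 fits with 1 library left out (adjusted p = 0.0127 to 0.293 by camera). let-7c was at -0.91 (SE 0.50), with 0 members past the threshold in either list, over all miRNAs or adjusted over the list alone. In in vivo EVs taken alone both of these lists pointed the other way.

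Within nuclear transfer EVs, 40 of 180 miRNAs differed between male (n = 7) and female (n = 5) conceptuses by edgeR, 24 higher and 16 lower in males. Among the lower, let-7b and miR-3596 have the same counts and those of miR-129 and miR-129-5p differ by 0.382%, so the 16 are at most 14 separate measurements. Entries that share reads in a fixed ratio, as miR-124a and miR-124b do, were not looked for here. The labels do not name the donor cells of nuclear transfer, so conceptus sex cannot be told apart from donor cell here. The DLK1-DIO3 group ranked higher in males at the preset correlation (camera adjusted p = 0.00107), a call lost with an estimated correlation (camera adjusted p = 0.630). Tested against no change, the group had a fry adjusted p = 0.0341. All 8 tested members were positive and 5 passed the threshold, 5 adjusted over the list alone. miR-154c rose by 4.45 on the log2 scale (SE 0.82, adjusted p = 0.00546 by edgeR), miR-411a by 3.25 (SE 0.70), miR-381 by 2.30 (SE 0.69) and miR-379 by 2.24 (SE 0.65), each above the female median in 7 of 7 males. The miR-302 and miR-371 clusters ranked higher at the preset correlation (camera adjusted p = 0.0224), a call kept in 8 of 12 fits with 1 library left out. It was lost with an estimated correlation (camera adjusted p = 0.630). Tested against no change, the clusters had a fry adjusted p = 0.0381, with 3 of 4 members past the threshold and 4 adjusted over the list alone. miR-371 rose by 3.91 (SE 0.76) in 7 of 7 males, miR-302a by 3.15 (SE 1.01) and miR-302b by 2.75 (SE 0.88) in 6 of 7. Such counts of males are no separate support, as the miRNAs were named for their differences in the same libraries. Other rises were miR-2404 at 4.68 (SE 0.93, adjusted p = 0.00546 by edgeR), miR-12034 at 4.38 (SE 1.00), miR-2463 at 3.33 (SE 0.93), miR-2892 at 3.33 (SE 0.80) and miR-9-3p at 2.87 (SE 1.00). Of these, miR-2892 is on the list of entries that overlap other small RNA classes.

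The let-7 family ranked lower in male nuclear transfer EVs at the preset correlation (camera adjusted p = 0.00107), a call lost with an estimated correlation (camera adjusted p = 0.630). Tested against no change, the family had a fry adjusted p = 0.0341. Of its members 0 of 9 were positive, 3 past the threshold and 6 adjusted over the list alone. let-7b was at -2.35 (SE 0.57, adjusted p = 0.0128 by edgeR), with a mean of 14.46 ± 0.81 log2 CPM (n = 5) in females and 11.76 ± 1.16 (n = 7) in males. let-7a-5p was at -1.84 (SE 0.50) and let-7e at -1.58 (SE 0.52), each of the 3 below the female median in 7 of 7 males. These counts too come from the libraries in which the miRNAs were named. The miR-10 and miR-99 or 100 families ranked lower at the preset correlation (camera adjusted p = 0.0494), a call lost with an estimated correlation (camera adjusted p = 0.670). Tested against no change, they had a fry adjusted p = 0.0722, with 1 of 7 members positive, 2 past the threshold and 3 adjusted over the list alone. The camera call was kept in 6 of 8 alternatives and in 4 of 12 fits with 1 library left out (adjusted p = 0.0202 to 0.174 by camera). miR-10a was at -2.40 (SE 0.58) and miR-99b at -1.76 (SE 0.53). Other falls were miR-184 at -3.83 (SE 1.2), miR-92b at -2.64 (SE 0.65), miR-30f at -2.42 (SE 0.72), miR-423-5p at -2.04 (SE 0.57), miR-129-5p at -1.98 (SE 0.58) and miR-200c, an epithelial miRNA, at -1.93 (SE 0.52). Mean log2 CPM of miR-184 lay closer together, at 8.51 ± 2.92 (n = 5) in females and 7.02 ± 1.4 (n = 7) in males, with a wide female spread. miR-2887 and miR-2904 together took 24.6 ± 16.2% (n = 5) of the counts in female and 46.6 ± 10.2% (n = 7) in male nuclear transfer EVs (exact two-sided permutation p = 0.0177). With that share as a covariate 0 miRNAs passed. DESeq2 called 61, limma voom 47, the fit of all 6 groups 20, library sizes without the 5 most abundant miRNAs 25 (19 higher, 6 lower) and leaving out 1 library 16 to 50. The count was 16 without male 3 or female 3, 20 without male 1, 21 without female 4, 24 without male 4 or 6 and 26 without male 5.

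**Figure D3:**
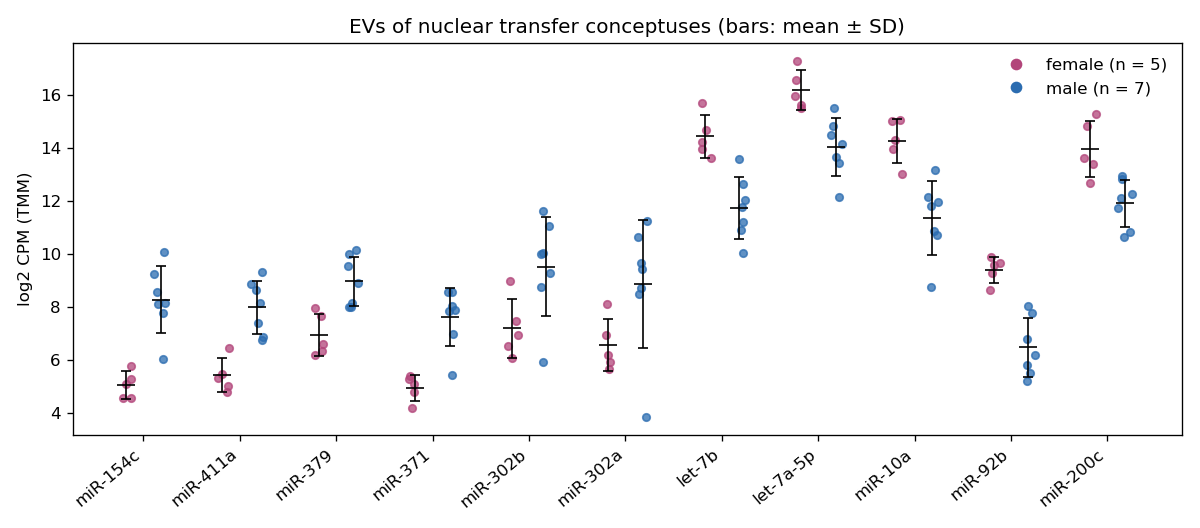
log2 CPM (TMM, y axis) of 11 miRNAs (x axis) in nuclear transfer EVs; points are libraries, female (n = 5) and male (n = 7), and bars are mean ± SD. miR-154c averages 5.06 in females and 8.28 in males, and let-7b 14.46 and 11.76.

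The same test in in vivo EVs alone and in IVF EVs alone called 0 miRNAs each by edgeR, with 0 and 1 at an unadjusted p under 0.05. The type by sex interaction called 0 miRNAs by edgeR (35 at an unadjusted p under 0.05), 0 by DESeq2 and 0 by limma voom. A sex difference particular to nuclear transfer was not shown. Its smallest p values belonged to miR-154c, miR-222, miR-2404, miR-11980 and let-7e, each with an adjusted p = 0.315 by edgeR.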

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

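Chosen only after the result was seen were the tests of count depth, shared source and carrying libraries for miR-124a and miR-1298 and the tests in endometrium that left out or thinned libraries or used the sample code digit. The test of the miR-2887 and miR-2904 share was chosen after it as well. The other splits of the libraries, the test of whether in vivo male replicate 1 stands alone, and the tests of depth and of sex in the other types for nuclear transfer EVs were written before their results were seen. The spread of the test of sex over resampled libraries was added after. The set around miR-124a at first also counted miR-218 and miR-138 as nearly absent from nuclear transfer EVs. They were left out of that statement when their 183 and 18 counts there were seen. A first limit for the exact test was replaced because 4 carrying libraries could not have reached 0.05.

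Single libraries stood apart from their groups in 15 of 195 groups of values tested, where chance gives 9.8. In log2 CPM, IVF female replicate 4 was highest of its 7 libraries for miR-124a (10.04), miR-124b (9.06) and miR-1298 (8.58). Nuclear transfer female replicate 3 was highest for miR-124a (4.87, from 8 counts), miR-124b (4.45, from 4 counts) and miR-320a (13.03), and it also had the highest EV total at 603.6 k counts. The other nuclear transfer females had no count of miR-124a or miR-124b. Nuclear transfer male replicate 5 was highest for miR-1298 (4.28, from 1 count), and male replicate 4 for miR-138 (7.26, from 18 counts), the other males having no count of either. Nuclear transfer male replicate 1 was lowest for miR-34c (6.69), miR-30f (4.60) and let-7d (5.99), male replicate 2, with no count of either, for miR-302a (3.84) and miR-302d (3.84), and male replicate 7 for miR-2892 (6.86). In endometrium, the type by sex interaction of 1 gene passed the threshold (adjusted p = 0.0141 by edgeR), its level under in vivo males and in vivo females lying on opposite sides of the other 4 groups.

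miR-124a, miR-124b and miR-1298 were nearly absent from nuclear transfer EVs and high in a few in vivo and IVF libraries. That nuclear transfer libraries were too shallow to show them is argued against. At the pooled rate of the others, 248 counts of miR-124b and miR-1298 would be due there and 8 were seen. Whether they have a shared source present in some libraries stays open: the median Spearman rho of 0.74 between miR-124b, miR-1298, miR-219-3p, miR-218 and miR-138 over the in vivo and IVF libraries decides nothing, because these were chosen for being high in the same libraries. Whether the few carrying libraries fell outside nuclear transfer by chance stays open: any miR-1298 count occurred in 9 of 16 in vivo and IVF libraries and 3 of 12 nuclear transfer libraries (exact two-sided Fisher p = 0.136). A difference in the conceptus between types stays open, as untested. So does a link of high values with low library totals. In vivo male 2, IVF male 3 and in vivo female 3, all high, held 39.3, 41.4 and 49.2 k counts. The lowest nuclear transfer total was 69.4 k. IVF female 4, also high, held 121.5 k.

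Endometrium under male in vivo conceptuses stood apart from that under male nuclear transfer conceptuses, with 56 calls, where the contralateral horn of in vivo male replicate 2 and unequal depth are argued against by 189 calls without the contralateral libraries and 46 after thinning to the shallowest library. The number of calls was 3 without in vivo male replicate 1, but 5, 6, 7 and 13 without nuclear transfer males 3, 4, 5 and 2 and 21 without in vivo male 3, so whether 1 library sets it stays open. Replicate 1 was not alone in its direction: at the 200 genes farthest apart in it (median 3.27 on the log2 scale there), in vivo male replicates 2 and 3 lay on its side by a smaller median of 0.64 (0.69 and 0.55), and the IVF males by -0.50, -0.20 and -0.05. The sample code digit 3, which all in vivo male libraries share, ended every call as a covariate, which the design nearly confounds with the group, yet 5 libraries of other groups with that digit deviated by a median of -0.03 (-0.22 to 0.26) at the 56 genes, whose median size of change was 1.49. What stays open is a difference between in vivo and nuclear transfer male pregnancies, as a hypothesis, beside unrecorded handling of the 3 in vivo male samples, which was not tested.

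Male and female nuclear transfer EVs differed in 40 miRNA entries, or at most 38 separate ones when nearly identical copies count 1 time. The labels do not name the donor cells, so a donor difference between the sexes stays open, as untested. Unequal total counts are argued against by 29 calls among 149 miRNAs after thinning to 69424 counts. Thinning does not even out the counts left beside miR-2887 and miR-2904, whose mean share was 24.6% in females and 46.6% in males. Unequal depth for the other miRNAs therefore stays open. Whether conceptus sex acts alike in every type stays open: 20% of the 40 (8) had the same sign in in vivo and IVF EVs together by edgeR and 47.5% from mean log2 CPM, the latter share running from 5% to 92.5% over 2000 resamples of libraries. The share of miR-2887 and miR-2904 stays open: with it as a covariate the median size of the 40 differences went from 2.41 to 1.5 on the log2 scale, the median SE from 0.70 to 0.73, all 40 kept their sign and 0 calls were left, because the folds shrank. Since that share differs between the sexes here, the design cannot say whether it may be a cause of the difference or another part of it, such as more degraded RNA in male EV samples.

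Other ways of splitting the same libraries were counted for each comparison. In endometrium, 5 of 100 splits gave at least the 2 calls of IVF against in vivo (highest other 7) and 15 of 100 at least the 1 call of the interaction (highest other 149), so chance is not excluded for either. Of 84 splits of the male in vivo and nuclear transfer libraries 1, the real one, gave 56 calls, the highest other giving 3. This is rare for 1 comparison alone, but it was picked from 9 within 1 sex or type after the counts were seen. Chance is therefore not excluded for it. In EVs, 6 of 100 splits gave at least the 1 call of nuclear transfer against in vivo (highest other 1), which leaves chance open. Of 100 splits 3 gave at least the 3 calls of nuclear transfer against IVF (highest other 30). That share is under 0.05 for this comparison alone, without correction for the other comparisons split in the same way. Besides, miR-124a and miR-124b are 1 measurement, and the exact test of carrying libraries above left chance open. Chance is thus not excluded for that number of calls or for these miRNAs. For sex within nuclear transfer 1 of 100 gave 40 calls (highest other 33). As that comparison was picked from 9 in the same way, chance is not excluded for it. Where the real split called 0, all 40 splits reach that number by definition. The highest other was 1 for nuclear transfer against in vivo, 1 against IVF and 52 for sex in endometrium. It was 37 for IVF against in vivo, 4 for sex and 1 for the interaction in EVs. What gave the splits with 149, 52, 37, 33 and 30 calls was not tested.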

How the results depend on the processing

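The alternatives added after seeing the data are thinning, the sample code digit, leaving out in vivo male replicate 1 with the contralateral libraries, identical entries, and both settings on miR-2887 and miR-2904. Every alternative of the pair of comparisons within male endometrium and within nuclear transfer EVs was added as well, and the others were planned. Most counts over all types differed between tools, the exceptions following below. For the pair of comparisons just named, limma voom called 48 and 47 where edgeR called 56 and 40. Where a value changed, the cause was not tested unless fewer libraries or genes entered the fit. Nuclear transfer against IVF in endometrium kept 0 calls under each alternative run and each library left out, as did EV sex over all types (except within nuclear transfer) and the EV interaction. EV depth limits what can be seen: a count of 0 in the shallowest library allows 3 counts of 39.3 k. Scaling by size factors moved the median EV log2 difference by 0.12 for IVF against in vivo, 0.07 for nuclear transfer against in vivo, -0.10 for nuclear transfer against IVF, 0.15 for sex and 0.02 for sex within nuclear transfer. Library sizes without the 5 most abundant miRNAs moved it in that order by 0.16, 0.05, -0.11, 0.09 and 0.34.

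Endometrial calls for IVF against in vivo (2) became 89 by DESeq2, 11 by limma voom, 103 without the contralateral libraries, 1 with the horn and 4 with the sample code digit as covariates. It became 0 thinned, 0 in the additive model, 5 with the pair of types alone, 0 within females, 4 within males and 0 to 37 with 1 library left out. They became 0 without IVF males 1 and 2, IVF females 1, 2, 4, 5 and 7, nuclear transfer male 2, in vivo female 1 or in vivo male 3. It was 12 without nuclear transfer male 6 and 37 without in vivo male 2. Nuclear transfer against in vivo (0) became 44 by DESeq2, 2 by limma voom, 106 without the contralateral libraries, 1 with the sample code digit, 56 within males and 0 to 7 with 1 library left out (7 without in vivo male 2, 6 without nuclear transfer female 3). Sex (0) became 57 by DESeq2, 508 without the contralateral libraries and 0 to 54 with 1 library left out (54 without in vivo male 2, 0 without any other). The interaction (1) became 212 by DESeq2, 4 by limma voom, 3 with size factors, 3 without the filter, 277 without the contralateral libraries. It became 60 with the horn, 0 with the sample code digit, 2 thinned and 0 to 237 with 1 library left out (0 without in vivo female 2, 237 without in vivo male 2). Without in vivo male 1 and the contralateral libraries, each of these counts was 0.

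Nuclear transfer against in vivo within males (56) became 501 by DESeq2 (240 higher), 95 without the filter, 189 without the contralateral libraries (57 higher), 275 with the horn and 0 with the sample code digit as covariates, 565 in the fit of all 6 groups (193 higher). It was 2 without in vivo male 1 and the contralateral libraries. With 1 library left out it ran from 3 (in vivo male 1) to 216 (in vivo male 2). It was 5, 6, 7 and 13 without nuclear transfer males 3, 4, 5 and 2, 21 without in vivo male 3, 29 without IVF male 1 and 30 without IVF male 2 or 3.

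EV calls for IVF against in vivo (0) became 10 by DESeq2, 22 by limma voom, 6 without the filter and 0 to 21 with 1 library left out (21 without IVF male 3, 0 without any other). Nuclear transfer against in vivo (1) became 6 without the filter, 3 with identical entries counted 1 time, 3 in the additive model. It became 0 by DESeq2, by limma voom, with the share covariate, with the pair of types alone, within females and within males, and 0 to 5 with 1 library left out. Those giving 0 were in vivo female 3, in vivo male 2, nuclear transfer females 1, 3, 4 and 5 and nuclear transfer males 1, 2, 5, 6 and 7. The count of 5 came without in vivo female 2. Nuclear transfer against IVF (3) became 5 without the filter. It became 0 by DESeq2, by limma voom, without miR-2887 and miR-2904, with their share as a covariate, with the pair of types alone, within females and within males, and 0 to 4 with 1 library left out. Those giving 0 were IVF females 3, 4, 5 and 7, IVF male 3, in vivo male 3, nuclear transfer females 1 to 5 and nuclear transfer males 3, 5, 6 and 7. The count of 4 came without nuclear transfer male 4. The adjusted p of miR-1298 against in vivo ran from 0.000153 to 0.300 over the alternatives that keep every library or drop a group of them, and from 0.00818 to 0.995 with 1 library left out. That of miR-124a against IVF ran from 3.83e-05 to 0.700 and from 0.0259 to 1. DESeq2, which gave no p for either, is not in these ranges. Sex (0) became 40 within nuclear transfer. That count became 61 by DESeq2 (38 higher), 63 without the filter (43 higher), 25 without the 5 most abundant (19 higher) and 0 with the share covariate. It became 20 in the fit of all 6 groups and 16 to 50 with 1 library left out (16 without nuclear transfer male 3 or female 3, 20 without male 1, 21 without female 4, 24 without male 4 or 6, 26 without male 5).

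Same-numbered libraries share a number alone: correlations of their deviations ran from -0.19 to 0.29 in endometrium and from -0.50 to 0.63 in EVs. A replicate block left 0 calls in endometrium for IVF against in vivo and the interaction, 1 within males, and 0 in EVs for nuclear transfer against in vivo and against IVF. It left 41 for sex within nuclear transfer.

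The single genes and miRNAs below had not passed the test in the contrast where their direction turned. TBL1X turned for IVF against in vivo (-0.01) at 0.01 by limma voom, 0.00 without the contralateral libraries, 0.02 without in vivo male 1 as well, 0.02 in the additive model and 0.17 within females (-0.02 to 0.02 with 1 library left out). It turned for nuclear transfer against in vivo (0.04) at -0.06 within males (-0.02 to 0.07) and against IVF (0.05) at -0.03 within females (-0.01 to 0.08). It turned for sex (0.02) at 0.00 by limma voom and -0.15 within IVF (-0.01 to 0.05). miR-148a and its copy miR-148d turned for IVF against in vivo (-0.02) at 0.14 by DESeq2 and with size factors, 0.32 by limma voom, 0.17 without the 5 most abundant, 0.03 with the share covariate, 0.02 in the additive model, 0.08 with the block, 0.00 with the pair of types alone and 0.09 within females (-0.23 to 0.21). They turned for sex (0.01) at 0.00 within in vivo and -0.14 within IVF (-0.09 to 0.31). miR-26a and miR-26c turned for nuclear transfer against in vivo (0.13) at -0.01 with the 10 CPM filter and with the block, -0.05 with identical entries counted 1 time and -0.60 within males (-0.17 to 0.40). They turned for IVF against in vivo (-0.28) at 0.24 with the share covariate (-0.53 to 0.04) and for sex (-0.35) at 0.06 within in vivo. miR-21-5p turned for nuclear transfer against in vivo (0.09) at -0.02 with the 10 CPM filter, -0.04 with identical entries counted 1 time, -0.01 with the block and -0.22 within males (-0.12 to 0.18). It turned for IVF against in vivo (0.19) at -0.23 within males (-0.03 to 0.32), for nuclear transfer against IVF (-0.10) at 0.01 within males (-0.27 to 0.01) and for sex (0.18) at -0.10 within IVF.

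miR-7 turned with the share covariate at -0.31, -0.24 and 0.07 for IVF against in vivo, nuclear transfer against in vivo and nuclear transfer against IVF. It was at -0.69 within females for nuclear transfer against in vivo (-0.11 to 1.39 with 1 library left out) and at -0.06 within in vivo for sex. let-7f turned with the share covariate at 0.08 for IVF and 0.15 for nuclear transfer against in vivo, where it was 0.69 within females (-0.54 to 0.06). It turned for nuclear transfer against IVF at -0.16 with the block and -0.34 within males, and for sex at 0.46 within in vivo. let-7a-5p turned for nuclear transfer against in vivo at 0.13 with the share covariate and 0.78 within females (-1.03 to 0.04), against IVF at -0.34 within males and for sex at 0.54 within in vivo. miR-2887 was at 0.04 against IVF with the share covariate, which holds it by construction, and miR-99b at 0.37 for nuclear transfer against in vivo within females. For sex within in vivo, miR-2904 was at -0.40, let-7e at 0.85, let-7b at 0.10, miR-30d at 0.22 and miR-30f at 0.99. Within IVF miR-411a was at -0.23 and miR-379 at -0.07. Of the lists that had passed, the miR-29 and miR-30 families turned against IVF with the replicate block (adjusted p = 0.970, 0.0209 to 0.246 with 1 library left out). They turned for sex within in vivo (adjusted p = 0.800, 0.00544 to 0.0966), as did the let-7 family for sex within in vivo (adjusted p = 0.572, 0.0127 to 0.293). The miR-302 and miR-371 clusters turned against IVF within males (adjusted p = 0.955, 0.000618 to 0.246). No list turned under another scaling or filter.

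Calls of lists by camera, counted first over the other settings and then over fits with 1 library left out, held as follows. The miR-10 and miR-99 or 100 families held in 10 of 11 and 26 of 28 for IVF against in vivo, in 10 of 11 and 28 of 28 for nuclear transfer against in vivo, and in 6 of 8 and 4 of 12 for sex within nuclear transfer. For nuclear transfer against IVF, the miR-302 and miR-371 clusters held in 8 of 11 and 17 of 28, the miR-29 and miR-30 families in 5 of 11 and 7 of 28, and the miR-2284 and miR-2285 families in 4 of 11 and 6 of 28. For sex, the let-7 family held in 8 of 11 and 12 of 28, the DLK1-DIO3 cluster in 9 of 11 and 28 of 28, and the miR-29 and miR-30 families in 8 of 11 and 25 of 28. For sex within nuclear transfer, let-7 and DLK1-DIO3 each held in 8 of 8 and 12 of 12, and the miR-302 and miR-371 clusters in 7 of 8 and 8 of 12.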

Other observations

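The test of EV against endometrium profiles below was written before its result was seen, and no test in this part was chosen after it. Beyond the groups described, 11 further miRNA lists did not pass camera in any of the EV contrasts. The miR-17 to 92 clusters, which drive proliferation, had 6 of 7 members positive in IVF against in vivo EVs (median 1.07 on the log2 scale, adjusted p = 0.0984) and 7 of 7 in nuclear transfer against in vivo (median 0.41, adjusted p = 0.176). The miR-15 or 16 and miR-497 family had 3 of 3 positive in both (median 1.79, adjusted p = 0.125; median 1.84, adjusted p = 0.206, with 1 member past the threshold adjusted over the list alone). Muscle miRNAs were all positive in nuclear transfer against IVF EVs (4 of 4, median 2.36, adjusted p = 0.106). The miR-34 and miR-449 family was negative in males in 2 of 2 members (median -1, adjusted p = 0.135). The miR-200 family of epithelia was positive in 5 of 5 members in nuclear transfer against IVF (median 0.53, adjusted p = 0.212) and negative in 5 of 5 in male nuclear transfer EVs (median -0.74, adjusted p = 0.0810), where miR-200c fell.

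Markers of other sources gave no list past the threshold. Blood cell miRNAs were positive in 8 of 9 members in IVF against in vivo (median 0.89, adjusted p = 0.237) and in nuclear transfer against in vivo (median 0.99, adjusted p = 0.346). Liver and serum miRNAs had a smallest adjusted p = 0.569 over the contrasts. X-linked miRNAs, of which miR-1298 is one, had medians of -0.17 for sex over all types (18 members, adjusted p = 0.283) and -0.57 within nuclear transfer (13 members, adjusted p = 0.218). Entries that overlap other small RNA classes had 9 of 13 members positive in IVF against in vivo (median 1.40, adjusted p = 0.271; 7 higher and 2 lower adjusted over the list alone, 0 over all miRNAs). The miR-183 cluster and the miR-21, miR-22 and miR-26 group had smallest adjusted p values of 0.458 and 0.262, both for sex over all types. The median and the camera direction differed in sign for the miR-183 cluster and liver miRNAs in IVF against in vivo, for muscle miRNAs in nuclear transfer against in vivo, for blood cell miRNAs in nuclear transfer against IVF and in sex. They also differed for the DLK1-DIO3 cluster in nuclear transfer against IVF, and for muscle miRNAs within nuclear transfer, none of which passed.

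A hypothesis from the design is that cows whose conceptuses released similar EV cargo have similar endometrium. Over the 27 animals with both libraries, distances between EV profiles and distances between endometrium profiles had a Spearman rho of 0.06, where 10000 shuffles of animals within groups had a 95% point of 0.15 (one-sided permutation p = 0.346). No relation was detectable between the profiles as a whole, and single miRNAs and their targets were not tested because the endometrial genes carry no names here.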
